A study of Mus musculus with 37 samples.

How the data were processed

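The data were Affymetrix whole-transcript arrays of DBA-lectin-positive duct and duct-like cells of the mouse pancreas, labelled from 100 ng of total RNA per the labels. The deposited table held values that are log2 by their range (2.03 to 14.15), for 34760 probe sets on 37 arrays, and 0 columns were left unused. The authors' summarization, background correction and normalization are not given in the sources used here. Array medians (5.93 to 6.14) and upper quartiles (7.30 to 7.57) nearly coincided, so the values were taken as normalized between arrays. No genome coordinates were used. No 2 columns were identical (0 pairs), and over all probe sets the correlation between arrays lay between 0.898 and 0.987.

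Probe sets were named from the platform table. Of the 34760, 11799 had no annotation there. Of the 22961 with an annotation, 21640 named 1 gene symbol, 21553 of which were matched by gene identifier and 87 were not, and 1321 named several symbols and were left out. Of the 954 genes with several probe sets the one with the highest mean over the 37 arrays was used, which left 19937 genes. Among genes that passed, another probe set moved the opposite way, with an unadjusted p under 0.05 in limma, for 3 genes. These were Cdk12 in saline day 3 against day 0, and Filip1l and Socs6 in saline day 5 against day 0. No probe set named Kras.

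Groups, comparisons, tests, 22 gene lists and most alternatives were fixed before the data were examined. Groups followed the labels. Each comparison was a contrast in limma (3.58.1, R 4.3.3; lmFit and eBayes, moderated t tests of either direction) with 1 mean per group, and p values were adjusted by the method of Benjamini and Hochberg over all 19937 genes, with a threshold of 0.05. The 21 saline and pancreatitis arrays, the 9 Kras experiment arrays, the 7 developmental arrays and, for the embryonic comparison with adults, 10 arrays formed 1 fit each. Changes between days were tested by F tests. The 3 contrasts of saline days 1, 3 and 5 with day 0 were added after seeing the data, to give the F test its directions. The labels give separate arrays of a group but do not say that each came from another animal, so p values measure the spread between these arrays.

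The lists held 637 genes, 584 of them measured, and covered duct, acinar, islet and progenitor genes, signalling and stress pathways, metabolism, proliferation and the cell types that could remain in the sorted fraction. They were tested with camera at a preset correlation of 0.01, adjusted over all 242 tests of lists in comparisons, beside camera with an estimated correlation and fry, which asks whether the genes of a list move 1 way on balance and compares them with no other genes. Of the 242 tests 111 were called at the preset and 0 with an estimated correlation. The lists of the saline contrasts were adjusted apart. With these included 141 lists were called, and fry kept 12 of the calls and lost 129. Means, medians and tests of a called list had the same sign unless stated.

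Named genes followed a rule: per comparison the 10 that rose and the 10 that fell most among those past the threshold whose groups did not overlap on any array, leaving out unnamed and predicted genes, olfactory and vomeronasal receptors and immune receptor segments. Up to 4 members past the threshold were added per called list, the 5 of smallest p where fewer than 5 genes passed, and in every comparison Prrx1, Sox9, Krt19 and Kras. For the F tests, which the rule did not cover, the 10 of smallest p were named. Genes named outside the rule, Tff1, Muc5ac, Xist, the Y-linked and the fetal genes, Krt15 and Krt5, and those shared by pairs of comparisons, were chosen after their values were seen.

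Alternatives were another quantile normalization, subtraction of array medians, leaving out the dimmest 40% of genes, eBayes with trend and robust, array weights, the mean of all probe sets of a gene, 1 fit of all 37 arrays, other control groups, age as a covariate, a threshold of 0.1 for the shared genes, and each array left out in turn. Where that left a group with 1 array, the array was assumed to vary like the other groups. The replicate numbers of the titles were checked as pairs: correlations of residuals between arrays of the same number were, among the groups compared that have 3 such pairs, all above 0.1 only for pancreatitis day 5 with saline day 5 (0.140 to 0.355) and Kras G12D 10 weeks with control (0.185 to 0.686). For embryonic day 14.5 with postnatal day 1 the correlation was 0.173, but groups of 2 have only 2 pairs, which share 1 value. The numbers entered as an alternative block. In data simulated with the spread of each comparison, log2 changes of 1 and 2 were recovered for 75% and 98% of genes in pancreatitis day 5. The shares were 52% and 90% in Kras G12D against control and 24% and 78% in embryonic day 16.5 against day 14.5. The simulated noise was drawn for each gene apart, which leaves out arrays that deviate together in many genes. These shares therefore need not hold for the real arrays.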

Results

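Gene expression was measured on 37 arrays of cells from the mouse pancreas, taken as duct cells by their binding of DBA lectin. This plant protein sticks to sugars on the duct surface. The labels give 14 groups from 3 experiments. In the first, adult mice received saline or cerulein, a secretagogue that overdrives the acinar cells and brings on acute pancreatitis, with 3 arrays each of saline at days 0, 1, 3 and 5 and of pancreatitis at days 1, 3 and 5. The second followed development, with 2 arrays of embryonic day 14.5, 1 of day 15.5, 2 of day 16.5 and 2 of postnatal day 1. In the third, an activated Kras allele (G12D) was switched on in the pancreas by a Pdx1-driven recombinase, with 3 arrays at 10 weeks, 3 at 20 weeks and 3 controls without the mutation, 2 of them of 10 weeks and 1 of 20 weeks. The title of the series asks which expression changes these settings have in common. Array medians lay between 5.93 and 6.14 on the log2 scale, and the number of arrays per group limited the precision. Changes are log2 differences ± SE and levels are log2 means ± SD. Acinar genes stood high in the sorted fraction. On the saline day 0 arrays the mean of the acinar list was 12.13 to 12.39, against 8.74 to 9.14 for the duct list. Whether a change below arose in duct, acinar or other cells of the fraction, or from a change in their shares, was not tested.

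The labels of the developmental and Kras arrays were set against genes that mark age and sex, chosen after the values were seen. The mean of 14 measured genes of fetal tissue, among them Afp, Igf2 and Dlk1, was highest on 7 arrays, and 0 of these were labelled embryonic or postnatal, though not every gene of the list was highest there. All 7 were labelled as Kras experiment arrays, 2 of them as controls. Their means were at least 6.53, against at most 5.92 on the other 30 arrays, and the arrays labelled embryonic or postnatal began at rank 8. Xist, which is expressed in females, and the Y-linked genes Uty, Kdm5d and Eif2s3y were both above the midpoint of their ranges (7.85 and 5.58) on all 7 and on 1 of the other 30. Tff1 and Muc5ac, secreted products of gastric surface cells and of early pancreatic neoplasia, were high on 6 arrays, with Tff1 at 11.1 or more against at most 7.46 elsewhere and Muc5ac at 8.03 or more against at most 5.67. These 6 arrays carried the labels embryonic day 16.5 (2), postnatal day 1 (2), Kras control (array 1) and Kras G12D at 10 weeks (array 1). Every group below follows its label, so each direction given for the developmental and Kras arrays holds for arrays of that label, whatever tissue they carried. These labels are in doubt, so such directions should not be read as effects of stage or of genotype.

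**Figure D1:**
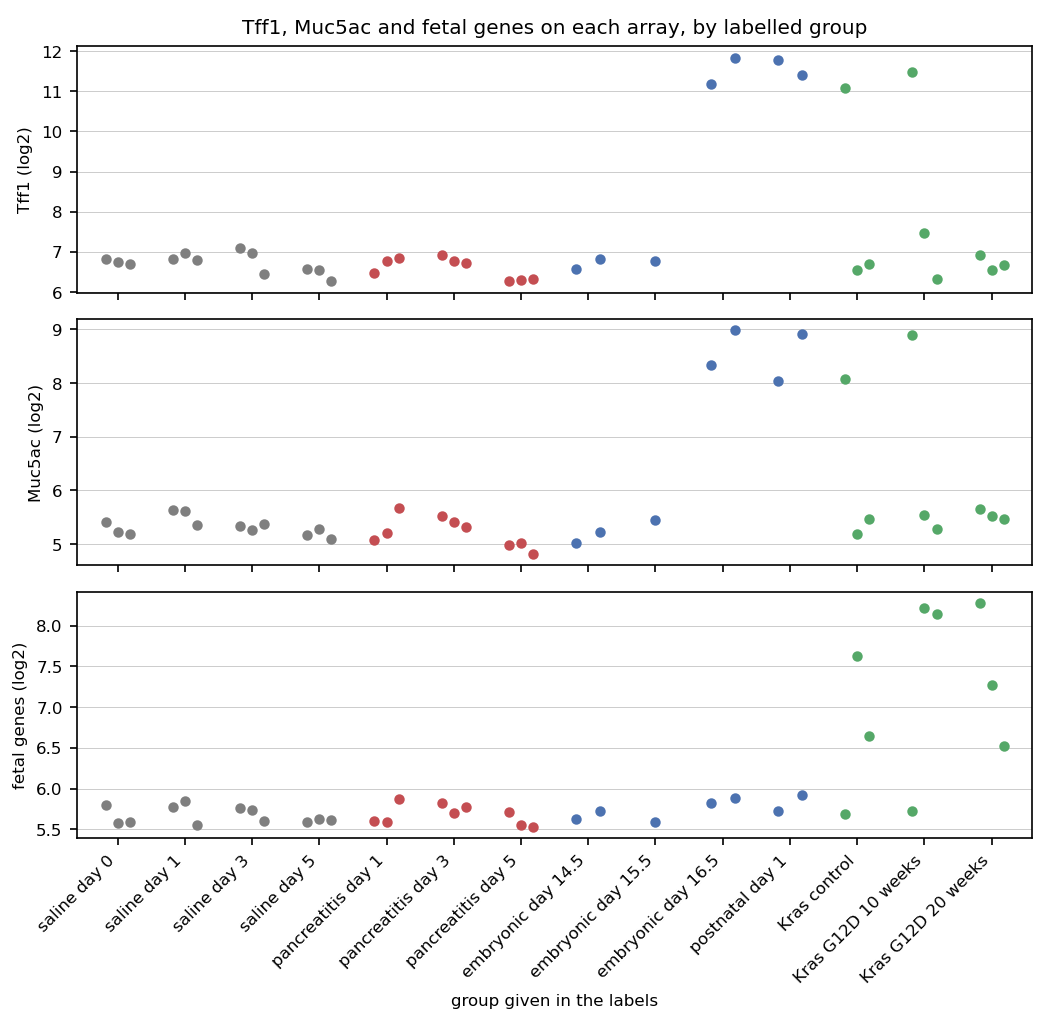
Level on the log2 scale of Tff1, of Muc5ac and of the mean of 14 fetal genes (vertical axes) on each of the 37 arrays, 1 point per array, by the group given in the labels (horizontal axis). Tff1 is at 11.1 or more on 6 arrays of 4 labelled groups, and the fetal mean is at 6.53 or more on 7 arrays, all with Kras experiment labels.

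At day 1 after cerulein, no single gene passed the threshold against day 1 saline. The 39 measured proliferation genes stood higher as a group, with a mean change of 0.36 and 32 of 39 positive, and 4 of them rose when p was adjusted over the list alone (adjusted p = 2.77e-11 for the list with a preset correlation, adjusted p = 0.487 with an estimated correlation). Genes of the unfolded protein response, which act when the endoplasmic reticulum is overloaded, had a mean change of 0.37 with 27 of 28 positive (adjusted p = 3.68e-06, adjusted p = 0.67 with an estimated correlation). Oxidative phosphorylation genes (mean 0.22, adjusted p = 1.21e-06) and immediate early genes (mean 0.21) were called upward, while interferon response genes (mean -0.21) and macrophage genes (mean -0.28) were called downward. With an estimated correlation the adjusted p was 0.67 for the oxidative phosphorylation, immediate early and interferon genes, and 0.805 for macrophages. The genes of smallest p were Prr11 (1.26 ± 0.31), Rpia (0.95 ± 0.22), Snord22 (0.88 ± 0.20), Acadl (-0.75 ± 0.18) and Ndc1 (0.52 ± 0.13), each with an adjusted p of 0.999. Prrx1, a homeodomain factor of mesenchyme and of duct progenitors, differed by 0.12 ± 0.25. With limma, 0 of 19937 genes passed and 734 had an unadjusted p under 0.05. Against saline day 0 in place of day 1, the mean of the unfolded protein response genes was -0.53 and that of oxidative phosphorylation -0.052. The mean was 0.17 for interferon and 0.13 for macrophage genes. Proliferation levels were 6.40 to 6.96 on the pancreatitis day 1 arrays and 5.83 to 5.97 on the saline day 0 arrays. On the matched saline day 1 arrays they were 6.17, 6.66 and 5.97, which overlapped with pancreatitis day 1. Immediate early levels of pancreatitis day 1 and saline day 0 overlapped, at 9.01 to 9.28 and 8.70 to 9.36. Without pancreatitis array 1 the means were 0.19 for proliferation, -0.067 for the unfolded protein response, -0.013 for oxidative phosphorylation, 0.13 for immediate early, -0.10 for interferon and -0.19 for macrophage genes. Of these calls only those of proliferation and immediate early genes held. Proliferation was 0.55 and 0.21 without saline arrays 2 and 3, the unfolded protein response 0.63 and oxidative phosphorylation 0.42 without pancreatitis array 3, and immediate early genes 0.35 without saline array 3. Calls were also lost for interferon (-0.22) and macrophage genes (-0.26) without pancreatitis array 3, and for interferon (-0.15) and immediate early genes (0.14) without saline array 1.

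At day 3, 59 genes rose and 30 fell against day 3 saline. Lgals4, an epithelial galectin, rose by 2.31 ± 0.27 (8.54 ± 0.50 against 6.23 ± 0.27, n = 3 and 3, adjusted p = 0.000949). Cftr, the chloride channel of duct cells, rose by 1.49 ± 0.32 (adjusted p = 0.0409), Glul, glutamine synthetase, by 1.87 ± 0.38, and the fatty acid enzymes Acot1 and Eci2 by 1.54 ± 0.24 and 1.45 ± 0.20. Ublcp1 (1.98), Smarca1 (1.83), Anxa9 (1.80), Ppil6 (1.65) and Tns1 (1.45) complete the 10 largest rises. Tmem45a fell (-3.37 ± 0.52, adjusted p = 0.00665), and so did Cd74, the invariant chain of antigen presentation (-1.55 ± 0.33, adjusted p = 0.0427). The other large falls were Klk1b1 (-1.78), Lgals9 (-1.49), Rnf225 (-1.40), Sycp1 (-1.22) and 4 small nucleolar RNAs, Snord15a, Snord55, Snora30 and Snora62 (-1.81 to -1.35). The macrophage list was called downward (mean -0.39, 1 of 32 fell, both over all genes and adjusted over the list alone, adjusted p = 0.00173), as were lymphocytes (mean -0.17, 0 of 19 fell) and erythroid cells (mean -0.13, 0 of 18 fell). With an estimated correlation the adjusted p was 0.798 for macrophages and 0.67 for lymphocytes and for erythroid cells. The macrophage call was lost without saline array 2 (mean -0.21) or pancreatitis array 1 (-0.31), the lymphocyte call without saline array 1 (-0.18) or 2 (-0.15) or pancreatitis array 2 (-0.12), and the erythroid call without saline array 1 (-0.12) or pancreatitis array 1 (-0.11) or 2 (-0.12). The duct list was not called (mean 0.11). Prrx1 (0.07 ± 0.25), Sox9 (0.12 ± 0.17) and Krt19 (-0.18 ± 0.24) did not pass.

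The day 3 differences depended on the day 3 saline arrays. Tmem45a rose by 3.49 ± 0.52, Klk1b1 by 1.93 ± 0.28 and Cd74 by 1.58 ± 0.33 in day 3 saline against day 0 saline, and Cftr fell by 1.43 there. Against day 0 saline the pancreatitis day 3 change was 0.13 for Tmem45a, 0.14 for Klk1b1, 0.033 for Cd74, 0.13 for Sycp1 and -0.12 for Ublcp1, and the count was 38. The lymphocyte and erythroid means were 0.14 and 0.049 against day 0 saline, and 0.047 and 0.046 against all 12 saline arrays. Saline day 3 array 2 had Xist at 4.48 and a Y-linked mean of 6.52. It was unlike every other saline or pancreatitis array, with Xist at 10.22 or more and a Y-linked mean of at most 3.87. The cause was not tested. The count of 89 was 395 without saline array 1, 41 without saline array 2, 27 without pancreatitis array 1 and 21 without pancreatitis array 2. Of the 20 named genes that passed, Lgals4, Eci2, Tmem45a, Klk1b1, Snora62 and Sycp1 also passed without any single array, while Cftr lost the threshold without any of the arrays but saline array 1, Glul without saline array 2 or pancreatitis array 1 or 2, and Cd74 without saline array 2 or 3 or pancreatitis array 1 or 2.

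At day 5, 281 genes rose and 16 fell against day 5 saline. Among the large rises were Tnc, a matrix protein of injury sites (3.25 ± 0.34, 9.67 ± 0.85 against 6.42 ± 0.67, n = 3 and 3, adjusted p = 5.79e-05), Vcan, a matrix proteoglycan (2.98 ± 0.34), and S100a4, a protein of motile fibroblasts and myeloid cells (2.59 ± 0.26). Prrx1 rose by 2.23 ± 0.25 (8.50 ± 0.32 against 6.27 ± 0.73, n = 3 and 3, adjusted p = 9.75e-05), and its change stayed between 1.97 and 3.10 and passed in all 16 alternatives. Of the 29 fibroblast and stellate cell genes 11 rose (19 rose and 1 fell adjusted over the list alone; mean 0.87, adjusted p = 4.01e-21, adjusted p = 0.27 with an estimated correlation), with Timp1 at 2.51 ± 0.43, the smooth muscle actin Acta2 at 2.31 ± 0.48 and Col6a3 at 1.84 ± 0.25. Of the 27 genes of epithelial-mesenchymal transition 7 rose (12 rose and 1 fell adjusted over the list alone; mean 0.66, adjusted p = 2.15e-11, adjusted p = 0.292 with an estimated correlation), among them the collagen cross-linking enzyme Lox at 2.31 ± 0.34.

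Myeloid and inflammatory genes rose in the same comparison. The scavenger receptors Msr1 and Cd36 rose by 3.34 ± 0.51 and 3.09 ± 0.43, the chemokines Ccl6, Pf4 and Ccl12 by 2.78, 2.76 and 2.60, and Ms4a6d by 2.60. Of the 32 macrophage genes 5 rose (19 adjusted over the list alone; mean 0.89, adjusted p = 8.4e-17, adjusted p = 0.415 with an estimated correlation), with the monocyte receptor Ccr2 at 2.09 ± 0.29 and Itgam at 1.96 ± 0.31. In the acute inflammatory list 4 of 32 rose (6 adjusted over the list alone; mean 0.55, adjusted p = 2.73e-06, adjusted p = 0.27 with an estimated correlation), the cytokine Il6 by 2.58 ± 0.28, Ccl7 by 2.23 ± 0.33, Ptgs2 by 2.19 ± 0.33 and Ccl2 by 2.15 ± 0.46. Proliferation genes were all positive (39 of 39, mean 0.64, adjusted p = 1.59e-21, adjusted p = 0.285 with an estimated correlation), and 3 rose over all genes, Melk, Rrm1 and Mcm5, and 18 adjusted over the list alone. Endothelial (mean 0.38), glycolysis (mean 0.34), mesothelial, neural and adipose (mean 0.30), ERK pathway (mean 0.23) and oxidative phosphorylation genes (mean 0.13) were called upward too. Their adjusted p was 0.285, 0.27, 0.535, 0.487 and 0.875 with an estimated correlation, in that order. In these lists 2 of 24, 2 of 21, 2 of 20, 2 of 29 and 0 of 29 genes rose, or 3, 7, 4, 2 and 0 adjusted over the list alone. Without saline array 1 the macrophage mean was 0.50, the oxidative phosphorylation mean 0.23 and the mesothelial call was lost (0.24), as it was without pancreatitis array 2 (0.20). Without saline array 3 the ERK pathway call was lost (0.13), and the oxidative phosphorylation call was lost without pancreatitis array 1 (0.12) and saline arrays 2 (0.077) and 3 (0.10).

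Agr2, a protein-folding enzyme of mucus-secreting cells, was among the 16 genes that fell at day 5 (-2.57 ± 0.42, 5.07 ± 0.19 against 7.64 ± 1.33, n = 3 and 3, adjusted p = 0.00189), but did not pass with all 37 arrays in 1 fit (adjusted p = 0.429) or against day 0 saline (-0.87, adjusted p = 0.148). Cuzd1, a zymogen granule protein, fell by 2.04 (SE 0.50, adjusted p = 0.046). Of 25 acinar genes 1, Cuzd1, fell, over all genes or adjusted over the list alone, and the acinar list was called downward (mean -0.29, adjusted p = 0.0165, adjusted p = 0.875 with an estimated correlation). The acinar mean was 0.22, -0.79 and -0.31 without saline arrays 1, 2 and 3 and -0.74, 0.028 and -0.17 without pancreatitis arrays 1, 2 and 3. The call held only without saline array 2 or pancreatitis array 1. Gbp9 (-1.40), Hmgcll1 (-1.27), Ppp1r36 (-1.10), Satb1 (-1.09), Akr1cl (-1.07), Capn6 (-0.96), Syn2 (-0.93), Pwwp3b (-0.90) and Psrc1 (-0.89) also fell. Akr1cl did not pass without pancreatitis array 2 (-0.68), nor Pwwp3b without saline array 3 (-0.59). The duct markers Sox9 (-0.23 ± 0.17) and Krt19 (0.59 ± 0.24) did not pass (adjusted p = 0.893 and 0.413). In limma 297 of 19937 genes passed and 1738 had an unadjusted p under 0.05, against 89 and 2780 at day 3, so day 5 led by the first count and day 3 by the other. The groups did not overlap for 18.2% of genes, where chance gives 10% on average for 3 arrays against 3. Saline day 1 and day 0 did not overlap for 19.2%, with 3 genes past the threshold, and saline day 3 and day 0 for 22.6%. Such a share therefore does not by itself mark an effect of pancreatitis. The count was 573 without pancreatitis array 1, 93 and 107 without pancreatitis arrays 2 and 3, and 128 and 137 without saline arrays 1 and 3. Of the 46 named genes that passed, 18 passed without any single array, among them Prrx1, Tnc, Vcan, S100a4, Il6, Msr1, Timp1, Lox and Agr2, while Cuzd1 and Acta2 did not pass without pancreatitis array 2 or 3 or saline array 1 or 3. Against day 0 saline it was 3590, and Satb1, Akr1cl, Psrc1, Ppp1r36, Pwwp3b and Syn2 then had positive changes of 0.61, 1.16, 1.07, 0.28, 0.23 and 0.035.

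**Figure D2:**
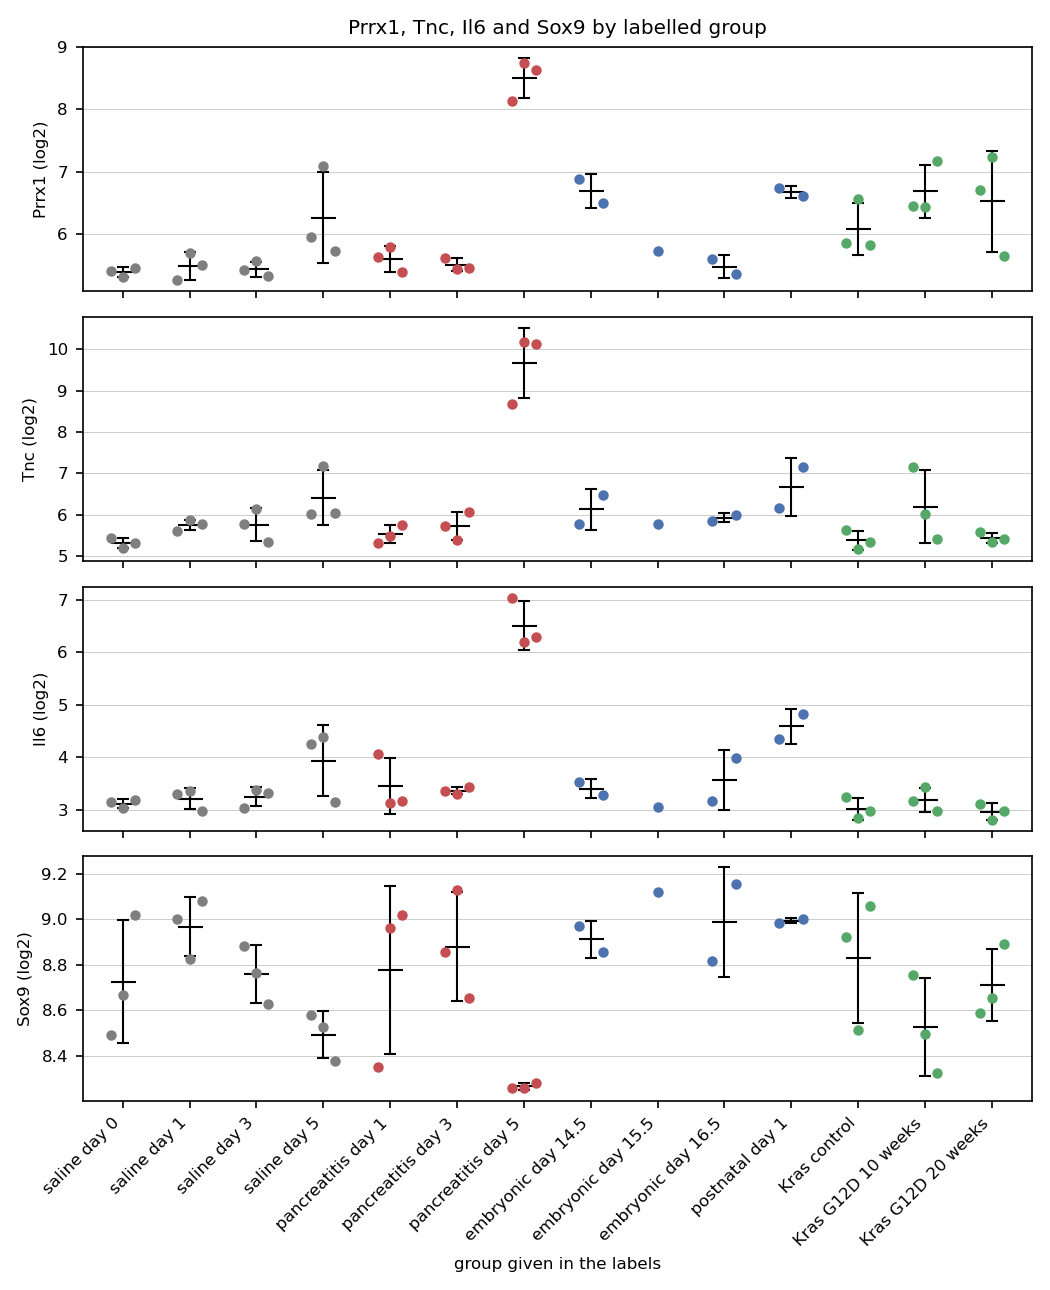
Level on the log2 scale of Prrx1, Tnc, Il6 and Sox9 (vertical axes) by the group given in the labels (horizontal axis), with 1 point per array and the mean and SD as black bars where a group has more than 1 array. Prrx1 was 8.50 ± 0.32 in pancreatitis day 5 and 6.27 ± 0.73 in saline day 5.

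Over days 1, 3 and 5 together only Aspn, a small proteoglycan of connective tissue, rose (1.15 ± 0.14, n = 9 and 9, adjusted p = 0.00247). With all 37 arrays in 1 fit Aspn did not pass (adjusted p = 0.285) and Il6 alone did (adjusted p = 0.0211). Il6 (0.98 ± 0.16), the lymphatic growth factor Vegfd (0.84 ± 0.14), Prrx1 (0.81 ± 0.14) and Fdft1 (0.54 ± 0.09) followed without passing, with adjusted p values of 0.0645 to 0.0741. Fibroblast genes had a mean change of 0.32 with 23 of 29 positive (adjusted p = 3.53e-09, adjusted p = 0.511 with an estimated correlation) and proliferation genes 0.31 with 38 of 39 positive (adjusted p = 3.56e-15, adjusted p = 0.388 with an estimated correlation). Adjusted over the list alone 9 fibroblast and 7 proliferation genes rose. At days 1, 3 and 5 the fibroblast means were 0.10, -0.021 and 0.87 and the proliferation means 0.36, -0.083 and 0.64. Without the day 5 arrays the fibroblast call was lost (0.040) and the proliferation mean was 0.14. The effect itself changed between days for 142 genes by an F test of limma. S100a4 led (adjusted p = 0.000395), followed by Lgals4, Rcn3, Tnc, Hcls1, Cd93, Vcan, Bnc2, Fnta and Aldh1a2 (adjusted p = 0.00152 to 0.00513). For Prrx1 the effect was 0.12 at day 1, 0.07 at day 3 and 2.23 at day 5, and the test of the difference passed (adjusted p = 0.00551). Without the day 5 arrays, an alternative chosen after seeing the data, 1 gene changed between days 1 and 3 and 0 passed over the mean of those days, where limma gave 1816 genes at an unadjusted p under 0.05 with all 3 days. The count of the mean over days was 47 without pancreatitis day 5 array 1, 34 without saline day 5 array 2, 13 without saline day 3 array 1, 4 without pancreatitis day 3 array 3, 3 without saline day 5 array 3, and 2 without pancreatitis day 1 array 3 or saline day 3 array 3.

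With single arrays left out, the count for the change between days was lowest and highest without a day 5 array. It was 356, 49 and 44 without pancreatitis day 5 arrays 1, 2 and 3, and 59, 225 and 49 without saline day 5 arrays 1, 2 and 3. It was 280 and 86 without saline day 3 arrays 1 and 2, 89 and 92 without pancreatitis day 3 arrays 1 and 2, and 86 without saline day 1 array 3.

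Expression in the saline arrays changed over the 4 days sampled, and most of all at day 5. Thbs1, an adhesive glycoprotein of injured tissue, rose by 3.64 ± 0.28 at day 5 against day 0 (10.60 ± 0.12 against 6.95 ± 0.66, n = 3 and 3, adjusted p = 7.86e-07). The gastric-type genes Ctse and Anxa10 rose by 4.17 ± 0.41 and 4.07 ± 0.42, the acute phase gene Lcn2 by 3.64 ± 0.49 and the fibroblast gene Postn by 3.42 ± 0.37. Of 39 proliferation genes 29 rose (33 adjusted over the list alone; mean 1.40, adjusted p = 1.12e-32, adjusted p = 0.085 with an estimated correlation), with Mki67 at 3.08 ± 0.38 and Top2a at 2.80 ± 0.42. The digestive enzyme genes moved the other way, 11 of 25 acinar genes fell (20 adjusted over the list alone; mean -1.35, adjusted p = 3.84e-10, adjusted p = 0.514 with an estimated correlation), with Pla2g1b at -2.85 ± 0.64, Gp2 at -2.77 ± 0.49 and Ctrc at -2.75 ± 0.54. Without day 5 array 2 the acinar mean was -0.86 and Pla2g1b, at -1.79, did not pass. Of 29 ERK pathway genes 9 rose (10 adjusted over the list alone; mean 0.60, adjusted p = 3.29e-07, adjusted p = 0.0837 with an estimated correlation), with Il1rn at 2.95 ± 0.33 and Egfr at 1.45 ± 0.19. Prrx1 rose by 0.86 ± 0.25 (adjusted p = 0.045) but did not pass without any single day 0 array or without day 5 array 2, where its change was 0.45.

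Marker genes of other cell types moved along in the day 5 saline arrays. Fibroblast genes had a mean change of 0.91 with 10 of 29 up (14 adjusted over the list alone), macrophage genes 0.74 with 5 of 32 up (9 adjusted over the list alone), islet genes -0.37 with 1 of 23 down (9 down and 1 up adjusted over the list alone) and endothelial genes -0.21 with 0 of 24 past the threshold either way. Their adjusted p was 0.395, 0.565, 0.388 and 0.724 with an estimated correlation. Without day 5 array 2 the fibroblast mean was 0.59 and the macrophage mean 0.44, without day 5 array 1 the macrophage mean was 1.13, and the endothelial call was lost without day 0 array 2 (-0.21) or 3 (-0.18) or day 5 array 1 (-0.18). By limma the F test over the 4 saline days called 4289 of 19937 genes, with Thbs1 (adjusted p = 6.95e-08), Itgav, Actn1, Slc26a9, Ddias, Abca1, Rgs5, Pik3r3, Nrp1 and Ctse at its head. Without saline day 5 arrays 2 and 3 in turn it called 2515 and 2006, and without all 3 day 5 arrays, chosen after seeing the data, 570. The single contrasts called 1146 genes at day 5 (905 up and 241 down), 434 at day 3 (126 up and 308 down, or 148 up and 158 down after another quantile normalization) and 3 at day 1. The day 5 count was 623 and 601 without day 0 arrays 1 and 2, and 438 and 493 without day 5 arrays 2 and 3, and 37 of the 57 named genes that passed there did so without any single array.

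Earlier saline arrays differed from day 0 in genes of several kinds. At day 3 Tmem45a rose by 3.49 ± 0.52, while the cystine transporter gene Slc7a11 fell (-3.17 ± 0.63), as did the glutamine transporter gene Slc1a5 (-1.65 ± 0.35), the desaturase gene Scd2 (-2.22 ± 0.28) and Sdha, a subunit of succinate dehydrogenase (-0.89 ± 0.13). At day 1 the 3 genes that passed all fell, Scd2 (-2.17 ± 0.28), Snord22 (-1.47 ± 0.20) and Lrrc4 (-1.39 ± 0.21). The unfolded protein response list was lower at day 1 (mean -0.90, 28 of 28 negative, 8 fell adjusted over the list alone) and at day 3 (mean -0.57, 26 of 28 negative), with an adjusted p of 0.388 and 0.662 with an estimated correlation. Without day 3 array 1 the day 3 mean of that list was -0.29. Of the day 1 genes, 0 passed without day 0 array 2 or without day 1 array 1. The day 3 count was 162, 23 and 112 without day 0 arrays 1, 2 and 3, and 760, 161 and 174 without day 3 arrays 1, 2 and 3, and of the 23 named genes that passed 7 passed without any single array, Scd2 and Sdha among them.

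Among arrays of the Kras experiment, no gene passed the threshold between those labelled G12D and those labelled control. Acinar genes were lower in the G12D arrays (mean -1.19, 25 of 25 negative) and so were unfolded protein response genes (mean -0.49, 28 of 28 negative) and duct genes (mean -0.44, 26 of 28 negative), while islet genes (mean 0.40), endocrine progenitor genes (mean 0.49) and fibroblast genes (mean 0.33) were higher. With an estimated correlation the adjusted p was 0.67, 0.627, 0.662, 0.487, 0.684 and 0.487, in the order given, and 0 genes of these lists passed adjusted over the list alone. With the preset correlation it ran from 9.26e-09 for the unfolded protein response to 0.00232 for endocrine progenitors. Apart from fibroblast genes (0.49) the means were nearer 0 without control array 1: -0.16 for acinar, -0.16 for unfolded protein response, -0.25 for duct, 0.17 for islet and 0.16 for endocrine progenitor genes. The acinar, islet and endocrine progenitor calls were then lost. The acinar mean was -1.93 without control array 3, -1.85 and -0.75 without G12D 10 weeks arrays 1 and 2 and -0.76 without 20 weeks array 1. Without control array 2 the duct mean was -0.73 and the endocrine progenitor mean 0.78, without control array 3 the unfolded protein response mean was -0.90, and without G12D 10 weeks array 3 the endocrine progenitor call was lost (0.35). Cnn2, a calponin of the actin cytoskeleton, had the smallest p, far from the threshold (1.19 ± 0.24, n = 6 and 3, adjusted p = 1.00), with Chl1 (0.67 ± 0.15), Fam149a (-0.70 ± 0.16), Zfp738 (0.60 ± 0.15) and Zswim7 (-0.49 ± 0.12) behind it. Prrx1 differed by 0.52 ± 0.35 and Sox9 by -0.21 ± 0.17. No probe set named Kras, so its own expression was not measured here. In limma 0 of 19937 genes passed and 351 had an unadjusted p under 0.05. Of the 9 arrays, 7 had the high fetal mean and the other 2, control array 1 and G12D 10 weeks array 1, the high Tff1.

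At 10 weeks the proteoglycan gene Lum was 2.19 ± 0.30 higher in arrays labelled G12D than in control (7.19 ± 0.23 against 5.00 ± 0.50, n = 3 and 3, adjusted p = 0.957), and Lox 1.24 ± 0.24 higher. Fibroblast genes had a mean change of 0.65 with 26 of 29 positive (1 rose adjusted over the list alone, adjusted p = 1.16e-13, adjusted p = 0.289 with an estimated correlation). Markers of pancreatic intraepithelial neoplasia (PanIN) and gastric-type mucus had a mean change of 0.40 at 10 weeks (22 of 30 positive, adjusted p = 0.0172, adjusted p = 0.875 with an estimated correlation), and 0 of them passed adjusted over the list alone. That mean was 1.37 without control array 1, and the call was lost without control arrays 2 (-0.15) and 3 (-0.029) and G12D 10 weeks array 1 (-0.79). It was 0.87 and 1.11 without G12D 10 weeks arrays 2 and 3. At 20 weeks Pdlim1 was lower (-1.27 ± 0.28, adjusted p = 0.998), and the PanIN list had a mean change of -0.92 (28 of 30 negative, 0 fell adjusted over the list alone, adjusted p = 9.09e-05, adjusted p = 0.797 with an estimated correlation). Between 20 and 10 weeks Lum differed by -2.40 ± 0.30 (adjusted p = 0.456), Sprr1a by -2.57 ± 0.47 and Perp by -1.36 ± 0.25. The PanIN mean there was -1.31 (0 fell adjusted over the list alone, adjusted p = 1.08e-08, adjusted p = 0.67 with an estimated correlation). It was -2.02 without G12D 10 weeks array 3, and without array 1 of that group it was -0.13 and the call was lost. Prrx1 differed by 0.60 ± 0.40 at 10 weeks, 0.44 ± 0.40 at 20 weeks and -0.16 ± 0.40 between them. With limma 0 genes passed in each, and 519, 506 and 922 had an unadjusted p under 0.05. Without the 2 arrays of high Tff1, chosen after seeing the data, the 20 week PanIN mean was 0.053 and 1 gene, Krt15, passed at 10 weeks. The 20 week mean was the same without control array 1 alone and -1.46 without control array 2. Without G12D 10 weeks array 1 alone, Krt15 and Krt5 passed at 10 weeks and between the ages, and Krt15 over both ages.

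Arrays labelled embryonic had lower Timp1, an inhibitor of matrix proteases, than those labelled postnatal day 1 (fell by 2.43, SE 0.22, 6.21 ± 0.24 against 8.64 ± 0.44, n = 5 and 2, adjusted p = 0.0387). The sialyltransferase gene St8sia6 (-2.84 ± 0.29, adjusted p = 0.0415) and Hsd11b1, which regenerates active glucocorticoid (-1.58 ± 0.15, adjusted p = 0.0387), fell as well. PanIN and gastric-type genes (mean -1.87, 2 fell adjusted over the list alone), acute inflammatory genes (mean -1.02, 12 fell adjusted over the list alone), macrophage genes (mean -0.82, 9 fell adjusted over the list alone, 32 of 32 negative) and ERK pathway genes (mean -0.65, 10 fell adjusted over the list alone) were called lower, and interferon genes higher (mean 1.06). With an estimated correlation the adjusted p was 0.511, 0.27, 0.388, 0.388 and 0.708. The interferon difference came from the day 14.5 arrays (list means 8.21 and 8.12) and the day 15.5 array (8.59). Both day 16.5 arrays (6.56 and 6.52) were level with the postnatal ones (6.57 and 6.51). Without the day 16.5 arrays, chosen after seeing the data, the interferon mean was 1.76 and the PanIN mean -2.82. Without postnatal array 2 the macrophage mean was -0.49. Prrx1 differed by -0.67 ± 0.39. The count of 3 of 19937 by limma, with 1931 at an unadjusted p under 0.05, was 95 without embryonic day 16.5 array 1 and 0 without any other single array of the 7, as well as with the replicate numbers as a block. Both embryonic day 16.5 arrays and both postnatal arrays had the high Tff1, and without the former, chosen after seeing the data, 996 genes passed.

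Within the embryonic labels, day 16.5 arrays differed from day 14.5 arrays by gastric genes. Gkn2 and Gkn1, secreted by the gastric surface, rose by 7.53 ± 0.23 and 6.50 ± 0.25 (Gkn2 11.87 ± 0.44 against 4.33 ± 0.13, n = 2 and 2, adjusted p = 0.000101), and Tff1 by 4.81 ± 0.26. The mast cell proteases Mcpt2 and Mcpt1 rose by 5.98 ± 0.35 and 5.45 ± 0.53, and the goblet cell genes Muc3 and Clca1 by 5.36 ± 0.43 and 4.10 ± 0.50. Of the 30 PanIN and gastric-type genes 16 rose (22 rose and 2 fell adjusted over the list alone; mean 2.40, adjusted p = 9.92e-23, adjusted p = 0.27 with an estimated correlation). Of 25 interferon response genes 16 fell (22 adjusted over the list alone; mean -1.63, adjusted p = 1.17e-27, adjusted p = 0.268 with an estimated correlation), with Ifit3 (-5.24 ± 0.36), Ifit1 (-3.02 ± 0.18) and Mx2 (-2.83 ± 0.18) among them. The regenerating genes Reg3a, Reg2 and Reg3b rose by 3.70, 2.77 and 2.31, the acinar genes Ctrc and Sycn by 3.79 and 3.23, and the gut hormone genes Pyy and Ghrl by 2.83 and 2.41. Postn (-2.14 ± 0.29) and Prrx1 (-1.21 ± 0.20, adjusted p = 0.0482) fell, and Prrx1 passed in 6 of 12 alternatives and in 0 of the 4 that left out an array. By limma 200 genes passed (79 up and 121 down), and the count was 88 and 42 without day 14.5 arrays 1 and 2, and 58 and 78 without day 16.5 arrays 1 and 2. Of the 34 named genes that passed 12 passed without any single array, among them Gkn2, Gkn1, Tff1, Mcpt2, Ifit3, Ifit1 and Mx2. Tff1 and Muc5ac were also high on 2 arrays with Kras labels. G12D 10 weeks array 1 (11.48 and 8.90) lay between the 2 day 16.5 arrays. Kras control array 1 (11.09 and 8.07) lay slightly under both. On 0 of the 4 arrays compared was the fetal mean above 5.92.

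Against adult saline day 0, arrays labelled embryonic were higher in the macrophage and proliferation lists and lower in the unfolded protein response list. Cd44, an adhesion receptor, rose by 2.28 ± 0.13 (9.73 ± 0.20 against 7.45 ± 0.07, n = 5 and 3, adjusted p = 4.72e-05), Tmem45a by 4.14 ± 0.39, the chemokine Ccl8 by 3.21 ± 0.24, Lcn2 by 2.80 ± 0.41 and Mki67 by 2.40 ± 0.41. Mki67 did not pass without saline day 0 array 1 or 2, embryonic day 14.5 array 2 or the day 15.5 array, nor Lcn2 without saline day 0 array 1 or 2. Of 39 proliferation genes 1 rose (25 adjusted over the list alone; mean 0.85, adjusted p = 1.02e-16, adjusted p = 0.545 with an estimated correlation), but with the Kras control arrays as the adult group the mean was -0.80. Of 32 macrophage genes 7 rose (22 adjusted over the list alone; mean 1.06, adjusted p = 4.01e-21, adjusted p = 0.289 with an estimated correlation), with the lysozyme gene Lyz2 at 1.93 ± 0.21. Of 28 unfolded protein response genes 5 fell (22 adjusted over the list alone; mean -1.04, adjusted p = 1.47e-16, adjusted p = 0.487 with an estimated correlation), with Syvn1 at -1.76 ± 0.34 and Hyou1 at -1.66 ± 0.31. The amino acid transporter genes Slc7a11 (-2.62), Slc7a3 (-2.27) and Slc1a5 (-1.88) and the serine synthesis gene Psat1 (-1.72) fell. Duct genes rose in 4 of 28 (5 adjusted over the list alone; mean 0.43, adjusted p = 1.18e-05, adjusted p = 0.511 with an estimated correlation), with carbonic anhydrase Car2 at 1.69 ± 0.32 and the bicarbonate carrier Slc4a4 at 1.12 ± 0.18. Of 27 genes of epithelial-mesenchymal transition 3 rose (5 adjusted over the list alone; mean 0.43, adjusted p = 2.03e-06, adjusted p = 0.27 with an estimated correlation), with Fn1 at 1.48 ± 0.26. Prrx1 differed by 0.62 ± 0.30 (adjusted p = 0.366).

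By limma 214 of 19937 genes passed in that comparison, 109 up and 105 down, and the experiments and the ages cannot be separated in it. The count was 1585 without the embryonic day 16.5 arrays, chosen after seeing the data, 1 with all 12 saline arrays as the adult group and 0 with the Kras control arrays, where Mki67 (-0.94), Slc7a11 (0.59), Slc7a3 (0.84), Chac1 (0.49) and Fn1 (-0.025) changed sign. It was 28 and 15 without saline day 0 arrays 1 and 2, 128 and 105 without embryonic day 14.5 arrays 1 and 2, 94 without the day 15.5 array and 467 without day 16.5 array 1. Of the 36 named genes that passed, Tmem45a, Ccl8, Gabrp, Cd44, Cldn2 and Lyz2 passed without any single array.

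The question of the series title, which genes change alike in injury, in the Kras model and in development, could not be answered here. The mean over days of pancreatitis called 1 gene by limma and G12D against control 0 (351 at an unadjusted p under 0.05). Their overlap with embryonic against adult saline was therefore fixed at 0 shared genes, with 0 expected by chance. The labels of the developmental and Kras arrays are also in doubt. Pancreatitis day 5 and the embryonic comparison with adult saline, which share no array, had 5 rising genes in common, Adh1, Lgmn, Sh3kbp1, Medag and Pycard, where 1.54 were expected. Across genes, which are not independent replicates, their changes had a Pearson r of 0.255 and a Spearman rho of 0.168. The only gene that rose at both day 3 and day 5 of pancreatitis was Aspn, where 0.832 were expected, while 2 genes moved in opposite directions and the changes of all genes had a Pearson r of -0.059. Pancreatitis day 3 and embryonic day 16.5 against day 14.5 ran against each other, with a Pearson r of -0.343 across genes, 3 genes in opposite directions and 1, Lgals4, up in both.

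**Figure D3:**
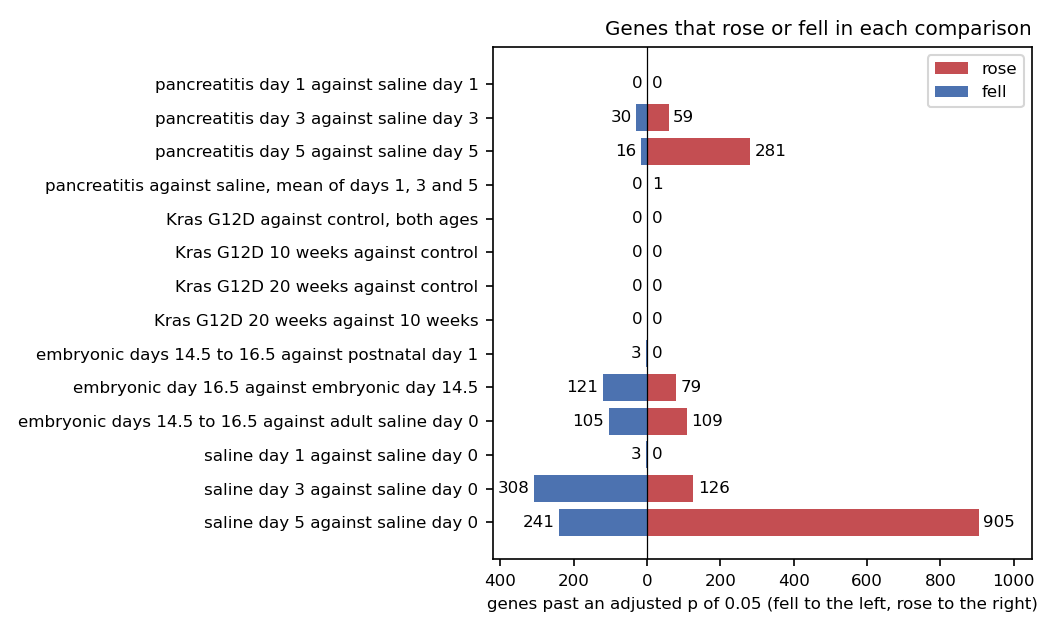
Number of genes past an adjusted p of 0.05 in each comparison (horizontal axis, fell to the left of 0 and rose to the right). Saline day 5 against day 0 gave 905 up and 241 down, and pancreatitis day 5 against saline day 5 gave 281 up and 16 down.

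**Figure D4:**
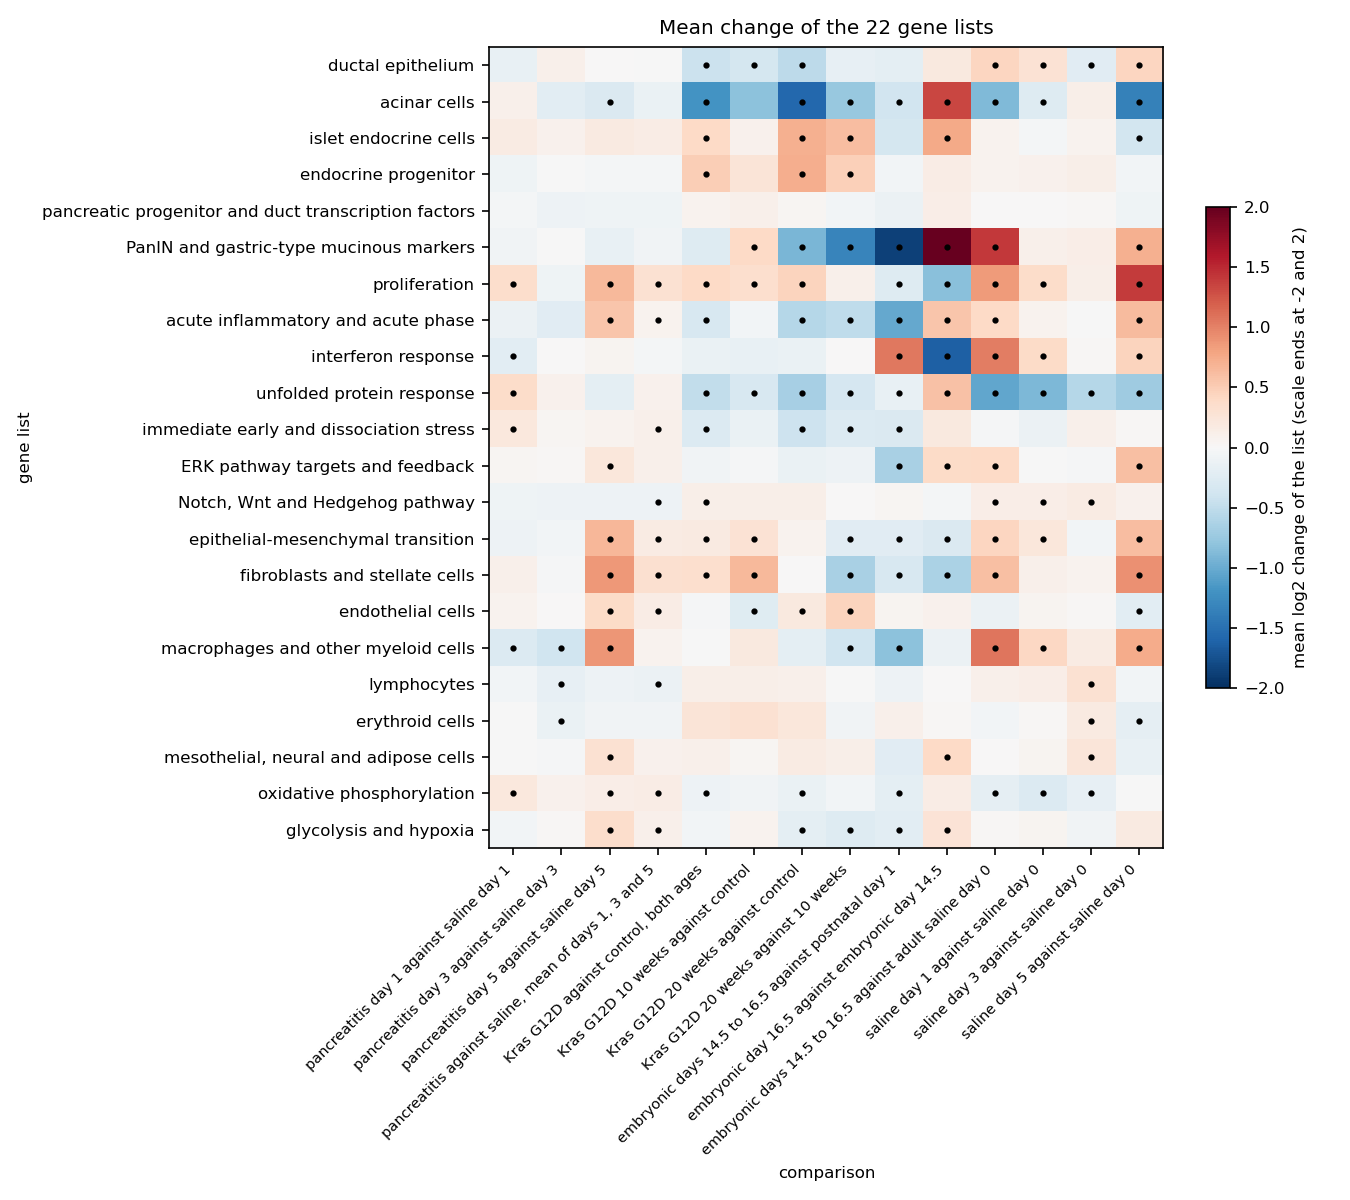
Mean log2 change of the measured genes of each of the 22 lists (vertical axis) in each comparison (horizontal axis), red for higher and blue for lower, with a dot where the list was called at the preset correlation of 0.01. With an estimated correlation 0 of the calls held.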

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

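The test of an onset of gastric genes at embryonic day 16.5, both tests of the day 5 saline arrays and the splits of saline days 1, 3 and 5 against day 0 were chosen only after the result was seen, as were the alternatives without the day 5 arrays, without the arrays of high Tff1 and without embryonic day 16.5. The gene lists of the fetal, sex and stomach tests were also chosen after values had been seen, but what each explanation predicts was written before its test was run.

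The mean of the fetal genes was highest on 7 arrays with Kras experiment labels, at 6.53 or more against at most 5.92 on the other 30 arrays. Fetal genes switched on by Kras G12D would leave the controls out, but 2 of the 7 were labelled Kras control. That argues against this explanation only if the control labels are right, and they are in doubt. Mislabelled samples met the prediction for both sexes: 7 of the 7 arrays had Xist and Y-linked genes above the midpoint, as a pool of littermates would. Of the other 30, 1 had both, postnatal array 2 (Xist 10.06, Y-linked mean 7.25). The exchange described next would make that array one of the Kras experiment, so it goes against the pattern. Wrong labels on the developmental and Kras arrays stay the candidate explanation, a hypothesis found and tested on the same data: the 7 arrays with developmental labels, Kras control array 1 and G12D 10 weeks array 1 would be the 9 of the Kras experiment, and the other 7 with Kras labels the developmental ones. In the order of deposit the fetal means of those last 7 arrays were 8.21, 8.28, 8.15, 7.28, 7.63, 6.53 and 6.64. Such steps would follow from 2, 1, 2 and 2 arrays of rising developmental age, if fetal genes decline with age. The 9 arrays before them held the 6 of high Tff1, as many as the labels give G12D arrays (6). Both matches were seen after the fact and were not tested. The arrays were not regrouped, but under this exchange the developmental comparisons would set Kras experiment arrays against each other or against adult saline, and the Kras comparisons would mostly hold developmental arrays.

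Tff1 and Muc5ac were high on 6 arrays that carried 4 different labels. Stomach tissue in the dissected pancreas would bring parietal and chief cell genes, and their mean was above that of all arrays outside the 6 on only 1 of the 6, Kras G12D 10 weeks array 1 (5.69). That bar was set by G12D 20 weeks array 1 (5.63). The next highest outside the 6, pancreatitis day 1 array 3 (5.54), lay under Kras control array 1 (5.62) and embryonic day 16.5 array 2 (5.56) as well. Other arrays of the 6 lay lower, at 5.20 to 5.51. The outcome thus hung on 1 array, and the test does not settle whether stomach tissue was present. Mislabelled samples, by which these arrays may be of the Kras model, need fetal genes to be absent from the developmental labels, and 0 of the 7 arrays of highest fetal mean were labelled embryonic or postnatal. Of the 16 Kras and developmental arrays 13 had their nearest array in the same labelled experiment, but embryonic day 16.5 array 2 and Kras control array 1 were nearest to each other (r = 0.982 across genes) and G12D 10 weeks array 1 to postnatal array 2 (0.975), and under the exchange above, which was known by then, it was 16 of 16. The test of an onset of gastric-type genes at embryonic day 16.5 was the 2 arrays labelled adult with Tff1 near that level. It only repeats the pattern and rests on labels in doubt. Such an onset needs fetal tissue on the arrays of day 16.5 and postnatal day 1. Their fetal means were 5.82 and 5.88 at day 16.5 and 5.73 and 5.92 at postnatal day 1, while pancreatitis day 1 array 3 reached 5.88. For these arrays the values argue against the onset, though the fetal genes were chosen after values had been seen.

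Saline arrays of day 5 stood apart from the other saline arrays. Fewer acinar cells in the sorted fraction, as the only change, would raise the markers of all other cell types alike. The median changes were instead -0.42 for islet, -0.16 for endothelial and 0.73 for fibroblast genes, a gap of 1.15 (SE 0.293). That SE was taken over the genes of the lists as if they were independent, and leaves out the spread between arrays. By array, islet means were 6.40, 6.19 and 6.05 at day 5 and 6.74, 6.46 and 6.56 at day 0. Fibroblast means were 6.93, 7.85 and 6.85 against 6.32, 6.22 and 6.37. The lists thus moved in opposite directions without overlap, which argues against acinar loss as the only change on these arrays. These values cannot exclude fewer acinar cells beside other changes: the acinar means were 11.93, 9.92 and 10.89 on the day 5 arrays, against 12.13 to 12.39 at day 0. A batch or label shared by the day 5 arrays stays open: the day 5 shift within saline and the day 5 shift within pancreatitis had a Pearson r of 0.769 across genes. An effect of 5 days of handling, shared by both treatments, was not tested and stays open as well.

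Splits of the arrays other than the labelled one were counted for comparisons of groups of at least 3 arrays. For 3 arrays against 3 there are only 10 splits, too few for a share under 0.05. The labelled and the highest other count were 89 and 4 at pancreatitis day 3 (1 of 10 as large), 297 and 67 at day 5 (1 of 10), 0 and 0 at day 1 (10 of 10), 0 and 168 for Kras G12D at 10 weeks (10 of 10), 0 and 0 at 20 weeks (10 of 10) and 0 and 0 between the ages (10 of 10). Against saline day 0 they were 3 and 2 for saline day 1, 434 and 1 for day 3 and 1146 and 0 for day 5 (1 of 10 each). The split with 168 genes set Kras control arrays 1 and 3 and G12D 10 weeks array 1 against the rest, which points to a structure of the samples. At day 5, where the numbers paired the arrays, the other splits that parted all pairs gave at most 1 gene. For the change of the effect between days, treatment labels were exchanged within each day (142, highest other 80, 1 of 100 splits as large). Such splits stand for no effect on any day, so they cannot decide whether an effect changed between days. Chance was excluded for saline over days (4289 and 1126, 1 of 100). The embryonic count against adult saline was reached in 2 of 56 splits (214 and 1136), and the 1136 came from embryonic days 14.5 and 15.5 against day 16.5 with the saline arrays, which again points to a structure of the samples. Chance was not excluded for the mean over days (1 and 43, 14 of 100). Where the labelled count was 0, as for Kras at both ages (highest other 10, 84 of 84) and the shared genes (highest other 0, 100 of 100), every split reaches it, so the splits decide nothing.

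The pancreatitis effect differed between days 1, 3 and 5 for 142 genes, tested by the difference itself, and for Prrx1 with an adjusted p of 0.00551. Some arrays lay far from the rest of a pool of several labels, all embryonic or all Kras G12D arrays, in 8 of the 50 sets of values tested, where chance gives about 1 in 20. Among the 6 arrays labelled Kras G12D, array 1 of 10 weeks stood apart in PanIN and gastric-type genes (9.66 against 5.86 to 6.34), acute inflammatory genes (7.96 against 5.33 to 5.94), macrophage genes (8.94 against 6.24 to 7.01), ERK pathway genes (7.34 against 6.77 to 6.96) and endocrine progenitor genes (5.80 against 6.84 to 7.43). In the 5 embryonic arrays, day 14.5 array 1 was low in endocrine progenitor genes (5.48 against 5.75 to 5.79), day 14.5 array 2 in oxidative phosphorylation genes (9.59 against 9.87 to 9.98), and day 16.5 array 2 was high in immediate early genes (9.29 against 8.88 to 8.98).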

How the results depend on the processing

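Alternatives without the day 5 arrays, without the 2 arrays of high Tff1 and without the embryonic day 16.5 arrays were chosen after seeing the data; the cause of the changes below was not tested. The 223 results of named genes that passed, a gene being counted in each comparison, kept their direction and their side of the threshold in 2597 of 3363 alternatives, lost the threshold in 745 and turned in direction in 21; the 22 of the F tests kept it in 496 of 526 and lost it in 30. For the 141 called lists the counts were 2029, 560 and 47 of 2636, and all 141 calls were lost with an estimated correlation and 129 with fry.

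The following counts moved by over 1.5 times. Pancreatitis day 3 (89) gave 173 with another quantile normalization, 18 with all 37 arrays in 1 fit, 52 with array weights, 38 against saline day 0 and 32 against all 12 saline arrays. Day 5 (297) gave 183 without dim genes, 165 in 1 fit, 1953 with weights, 3590 against day 0 and 5207 against all saline arrays, and day 1 (0) gave 3 and 1 with those controls. The mean over days (1) gave 22 with weights, 4 with the mean of probe sets, 235 and 49 with those controls and 0 without day 5, and in 1 fit Il6 took the place of Aspn. The change between days (142) gave 84 without dim genes, 63 in 1 fit, 527 with weights and 1 without day 5. Saline over days (4289) gave 7994 with weights and 570 without day 5. Saline contrasts gave, for day 1 (3), 5 after quantile normalization, 5 without dim genes and 199 with weights, for day 3 (434), 152 in 1 fit and 734 with weights, and for day 5 (1146), 542 and 3812. Kras G12D at 10 weeks (0) gave 4 in 1 fit and 20 against 10 weeks (0) gave 10; without the 2 arrays of high Tff1 both ages, 10 weeks and 20 against 10 weeks (0 each) gave 1 each. Embryonic against postnatal (3) gave 9 with medians subtracted, 12 with trend and robust, 72 in 1 fit, 8 with weights, 276 with the mean of stage means and 996 without day 16.5. Embryonic day 16.5 against 14.5 (200) gave 132 with weights. Embryonic against adult saline (214) gave 85 in 1 fit, 435 with weights, 1 with all saline arrays, 0 with Kras controls and 1585 without day 16.5. With the replicate block, the pairing by number, embryonic against postnatal gave 0 and saline day 1 gave 5.

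Directions of the test turned as follows (values are the log2 change, for lists the mean). Against saline day 0, at day 1: interferon 0.17, unfolded protein response -0.53, macrophages 0.13 and oxidative phosphorylation -0.052; at day 3: Ublcp1 -0.12, Tmem45a 0.13, Klk1b1 0.14, Cd74 0.033, Sycp1 0.13, lymphocytes 0.14 and erythroid cells 0.049; at day 5: Ppp1r36 0.28, Satb1 0.61, Akr1cl 1.16, Syn2 0.035, Pwwp3b 0.23 and Psrc1 1.07; over days: Notch, Wnt and Hedgehog genes 0.028 and lymphocytes 0.014. Against all 12 saline arrays, at day 3 lymphocytes were 0.047 and erythroid cells 0.046, and at day 5 Satb1 0.10, Akr1cl 0.55, Pwwp3b 0.0013 and Psrc1 0.47. Without day 5, over the mean of days, acute inflammatory genes were -0.17, epithelial-mesenchymal transition genes -0.073 and glycolysis genes -0.013. With array weights, glycolysis at 20 weeks was 0.031 and acinar genes between the ages 0.31. Against the 20 week control alone, acinar genes at 20 weeks were -0.10 with a test pointing upward, unfolded protein response 0.15 and immediate early genes 0.073. Without the arrays of high Tff1, PanIN genes at 20 weeks were 0.053 and proliferation -0.22, and between the ages acinar genes were 0.55, endocrine progenitors 0.021, acute inflammatory genes 0.34 and macrophages 0.42. With Kras controls as the adult group, Mki67 was -0.94, Slc7a11 0.59, Chac1 0.49, Slc7a3 0.84, n-R5s136 0.11, Fn1 -0.025, acinar genes 1.17, proliferation -0.80 and Notch genes -0.023. Without embryonic day 16.5, proliferation against postnatal was 0.070. The mean alone changed sign, with the call lost, for oxidative phosphorylation over days against saline day 0 (-0.0033), PanIN genes at 10 weeks with controls of 10 weeks only (-0.029), glycolysis at 20 weeks against the 20 week control (0.00075), immediate early genes between the ages without the arrays of high Tff1 (0.0010), and unfolded protein response (0.0049) and macrophage genes (0.0037) between the ages with array weights.

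Leaving out 1 array at a time, counts ranged from 0 to 0 for pancreatitis day 1, 21 to 395 for day 3, 93 to 573 for day 5, 1 to 47 for the mean over days, 44 to 356 for the change between days, 2006 to 4568 for saline over days, 0 to 3, 23 to 760 and 438 to 1187 for saline days 1, 3 and 5, 0 to 1 for Kras at both ages, 0 to 2 at 10 weeks, 0 to 0 at 20 weeks, 0 to 2 between the ages, 0 to 95 for embryonic against postnatal, 42 to 88 for day 16.5 against 14.5, 15 to 467 for embryonic against adult saline and 0 to 0 for the shared genes. Means of lists whose test turned in direction ranged from -0.067 to 0.63 for unfolded protein response at day 1 and -0.79 to 0.22 for acinar genes at day 5. For Kras at both ages they ranged from -0.27 to 0.97 for proliferation, -0.75 to 0.22 for acute inflammatory, -0.51 to 0.12 for immediate early and -0.18 to 0.0070 for oxidative phosphorylation genes. At 10 weeks the ranges were -0.32 to 1.06 for proliferation, -0.73 to 0.0096 for unfolded protein response and -0.79 to 1.37 for PanIN genes, and at 20 weeks -0.22 to 1.02 for proliferation and -0.047 to 0.37 for endothelial genes. Between the ages they were -1.64 to 0.55 for acinar, 0.021 to 0.74 for endocrine progenitor, -0.98 to 0.34 for acute inflammatory and -0.92 to 0.42 for macrophage genes, and for proliferation in embryonic against postnatal -0.67 to 0.16. The mean alone changed sign, with the call lost, for oxidative phosphorylation at pancreatitis day 1 without pancreatitis array 1 (-0.013) and at saline day 3 without day 3 array 1 (0.024), PanIN genes at 10 weeks without control arrays 2 (-0.15) and 3 (-0.029) and at 20 weeks without control array 1 (0.053), immediate early genes between the ages without G12D 10 weeks array 1 (0.0010), and unfolded protein response in embryonic against postnatal without embryonic day 14.5 array 2 (0.0016) or postnatal array 2 (0.023). The alternatives of the shared genes kept a count of 0.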

Other observations

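Transcription factors of pancreatic progenitors and duct, a list of 28 measured genes that includes Pdx1, Hnf1b, Onecut1 and Gata6, were called in 0 of the comparisons, with mean changes between -0.12 and 0.13. At pancreatitis day 5, 23 of the 28 were negative (mean -0.09). Prrx1, a member of this list and of the epithelial-mesenchymal transition list, rose there by 2.23 ± 0.25. The duct list itself had a mean of 0.01 there, with 0 of 28 genes past the threshold. Prrx1 was 8.13, 8.74 and 8.63 on the pancreatitis day 5 arrays, where the fibroblast list mean was 7.80, 8.22 and 8.24. On the saline day 5 arrays Prrx1 was 5.96, 7.10 and 5.73, and the fibroblast mean 6.93, 7.85 and 6.85. Whether Prrx1 rose in duct cells or in fibroblasts of the sorted fraction was not tested.

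In saline day 1 against day 0 the interferon response genes stood higher (mean 0.38, 23 of 25 positive, 3 rose adjusted over the list alone, adjusted p = 3.17e-05, adjusted p = 0.388 with an estimated correlation). At saline day 3 lymphocyte genes stood higher (mean 0.31, 18 of 19 positive, 6 rose adjusted over the list alone, adjusted p = 0.0011, adjusted p = 0.388 with an estimated correlation), with the B cell gene Ms4a1 at 0.60 ± 0.15. At saline day 5 the chloride transporter gene Slc26a9 rose by 3.47 ± 0.32 and Clca3a2 and Clca3a1 by 3.38 and 3.35, beside Ctse. Hamp2 (-2.48) and Retnla (-2.97) fell. These are single genes, and no list of secretion genes was tested.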
